A study of Homo sapiens with 16 samples.

How the data were processed

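Chromatin immunoprecipitation with sequencing was done, per the labels' protocols, on formaldehyde-crosslinked, sonicated chromatin of TC-32 and TC-71 cells. Antibodies against BORIS, SMC1 and H3K27ac and an input were used in 2 samples each per line, 16 samples in all. The labels do not say whether the 2 samples came from separate cultures. The submitters' processing notes name STAR 2.5.1b, SAMtools 1.3.1, Picard, deepTools 2.2.4 and MACS2 2.1.1 and the build hg19, without roles or settings. The parameters of mapping, duplicate removal and peak calling, and how replicates were combined, are not given in the sources used here. Both samples of a line and antibody point to the same list per the labels, so values per replicate were not analysed here.

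The authors deposited BORIS and SMC1 as narrow peaks with summits and H3K27ac as broad domains. For each peak the deposited lists give a score, which is 10 times the −log10 q without its decimals, a fold enrichment over the background from input, a −log10 p and a −log10 q. The smallest deposited −log10 q was close to 2 in the SMC1, H3K27ac and TC-71 BORIS lists. These values belong to the authors' peaks and were used only to describe, rank or filter peaks within a list, since lists called separately differ in depth and enrichment. The depth per sample is unknown from peak lists, and a deeper or better enriched library gives a longer list.

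Narrow peaks listed with several summits were counted as 1 interval with the values of the summit with the highest −log10 q, which turned 552 listed summits into 534 TC-71 BORIS intervals. Likewise 34320 listed SMC1 summits of TC-32 and 18455 of TC-71 were reduced to distinct intervals. Only chromosomes 1 to 22 and X were used, which left out 30 intervals over all lists. No interval (0) reached past an hg19 chromosome end, while 957 reached past the ends of the same chromosomes in GRCh38. Coordinates are hg19, counted from 1. Cytogenetic bands and their staining came from the hg19 band table in circlize 0.4.16, and chromosome lengths from GenomeInfoDb 1.38.1. The gene table given with the data is of GRCh38.p14, another build, so no gene was assigned to a peak. Planned analyses of promoters, of gene lists and of CTCF-type motifs were not run. Genes mentioned with a band are textbook background and were not tested for overlap.

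Overlap meant at least 1 bp in common. Shares carry exact (Clopper-Pearson) 95% intervals, which cover counting error only. TC-71 BORIS sites were placed 1000 times, and SMC1 and H3K27ac lists 100 times, at random on their own chromosomes outside centromeric, variable and stalk bands. Placement was uniform and not matched for gene density, mappability or active chromatin. Rank quartiles and deciles follow −log10 q within a list. Rank-matched shares weight the peaks without BORIS by the rank deciles of those with BORIS. H3K27ac domains within 12.5 kb were stitched, ranked by the sum of length times fold enrichment, and called top clusters above the point where the scaled rank curve has a slope of 1. Named peaks follow a rule fixed before the data were examined: every TC-32 BORIS peak, the 20 TC-71 BORIS peaks with the highest −log10 q, the 10 highest line-specific peaks per line for SMC1 and H3K27ac, and the 10 highest-ranked clusters with the 10 highest lacking a domain in the other line. The text names a part of each. No p-value between lines was computed, because the deposited lists give no values per replicate.

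Alternatives were a −log10 q of at least 5, 50% of a peak covered, summits within 500 bp, lists of equal length (highest −log10 p first), merging within 1 kb, stitching at 5 kb, and clusters ranked by covered length. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The overlap code was tested on simulated lists of 8000 sites for SMC1 and 8000 for H3K27ac sharing, in which 59.3% and 59.4% of sites were shared, and it made 0 wrong calls.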

Results

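TC-32 and TC-71 are established Ewing sarcoma cell lines; Ewing sarcoma is a bone and soft tissue tumour of young people, usually driven by a fusion of EWSR1 with an ETS factor. The labels place TC-32 at diagnosis and TC-71 after chemotherapy. Chromatin immunoprecipitation with sequencing was run in each line with antibodies against BORIS, SMC1 and H3K27ac, with input chromatin alongside, giving 16 samples with 2 per line and antibody. BORIS (CTCFL) is a paralog of the insulator protein CTCF that is normally restricted to the germ line, SMC1 is a subunit of the cohesin ring, and H3K27ac marks active promoters and enhancers. The deposited data analysed here are 6 peak lists, 1 per line and antibody, each called against the input of the same line. On chromosomes 1 to 22 and X these hold 6 BORIS peaks, 32720 SMC1 peaks and 36355 H3K27ac domains in TC-32. The corresponding lists of TC-71 hold 534 BORIS peaks, 18264 SMC1 peaks and 26334 H3K27ac domains. Because the 2 replicates share a list, no value has a replicate error, no test between the lines was possible, and the exact (Clopper-Pearson) 95% intervals given with shares cover counting error only. Read depth is unknown from these lists.

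The first comparison asked where BORIS was found in each line. BORIS binding was listed almost entirely in TC-71, with 534 peaks against 6 in TC-32, an 89-fold difference in list length that runs opposite to the other antibodies. The TC-32 lists were 1.79 times longer for SMC1 and 1.38 times longer for H3K27ac. TC-71 BORIS peaks were short, with a median width of 121 bp, and together covered 70.5 kb. They were dense on gene-rich chromosomes, at 0.677 per Mb on chromosome 19, 0.421 on chromosome 16 and 0.357 on chromosome 17. The bands with most sites were 16p13.3 with 12, 14q32.33 and 19q13.2 with 9 each, and 12q13.13, 14q11.2 and 17q25.3 with 8 each. Raising the threshold to a −log10 q of at least 5 left 458 TC-71 peaks and 3 TC-32 peaks.

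Of the 6 TC-32 BORIS peaks, 5 lay at a TC-32 SMC1 peak and 3 at a TC-32 H3K27ac domain. The strongest was at 17p11.2 (chromosome 17, 18967108 to 18967183, hg19), with an authors' fold enrichment of 12.4 over input, at SMC1 in TC-32 and in none of the TC-71 lists. Only 2 of the 6 were BORIS peaks in TC-71 as well. They were at 21p11.2 (chromosome 21, 9825844 to 9825974) and at 12q21.31 (chromosome 12, 82752200 to 82752289). At 21p11.2 the fold enrichment was low, at 2.95 in TC-32 and 2.59 in TC-71, against list medians of 5.44 and 5.98. This peak lay in no SMC1 or H3K27ac list of either line. At 12q21.31 the folds were 4.81 and 5.51. The remaining 3 were at 17q22 (chromosome 17, 56736475 to 56736563), 11q12.3 (chromosome 11, 62609088 to 62609252) and 1q21.2 (chromosome 1, 147994230 to 147994329).

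The next comparison asked whether TC-71 BORIS sites carry cohesin and acetylation. In TC-71, 342 of the 534 sites lay at an SMC1 peak (64.0%, interval 59.8 to 68.1%) and 303 in an H3K27ac domain (56.7%, 52.4 to 61.0%). Sites placed at random on the same chromosomes met SMC1 in a mean of 0.236% and H3K27ac in a mean of 1.94% of cases, with maxima of 1.12% and 4.12% over 1000 placements. These uniform placements were not matched for gene density or active chromatin, so they are a low bar. At the 342 sites with SMC1 the median distance between BORIS and SMC1 summits was 16 bp, and 90.6% were within 50 bp; the overlap of these short peaks itself keeps their summits close. The sites divided into 179 with SMC1 alone (33.5%, 29.5 to 37.7%), 163 with SMC1 and H3K27ac (30.5%, 26.6 to 34.6%), 140 with H3K27ac alone (26.2%, 22.5 to 30.2%) and 52 with neither (9.74%, 7.36 to 12.6%). The 163 sites with both marks were fewer than the 194 that independent marks would give. These classes rest on an overlap of at least 1 bp. With a window of 500 bp around the BORIS summit, the share with H3K27ac in TC-71 was 69.7%. Some sites classed as without H3K27ac therefore lay beside a domain.

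**Figure D1:**
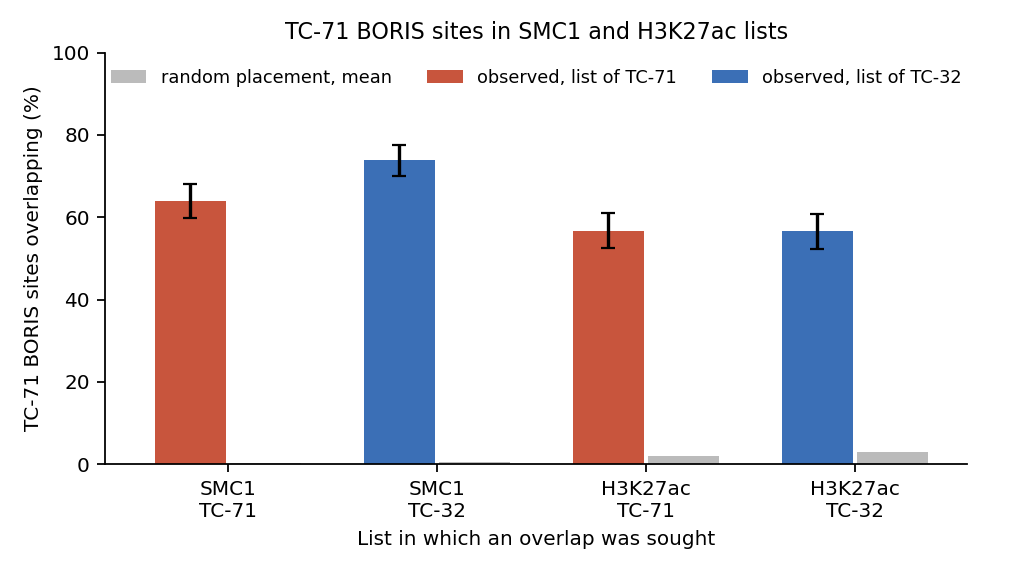
Share of the 534 TC-71 BORIS sites (vertical axis, percent) that overlap an SMC1 peak or H3K27ac domain listed in TC-71 (red) or TC-32 (blue), with exact 95% intervals as error bars, beside the mean of 1000 random placements (grey). The observed shares lie between 56.6% and 74.0%, and the means of the random placements between 0.236% and 2.89%.

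Acetylation was more frequent at high-ranked than at low-ranked BORIS sites. H3K27ac was present at 66.4% (57.8 to 74.3%) of the highest quartile of TC-71 BORIS sites and at 45.9% (37.2 to 54.7%) of the lowest, with 60.9% and 53.7% between. SMC1 was present at 56.7% (47.9 to 65.2%) of the highest quartile and 67.7% (59.0 to 75.5%) of the lowest in TC-71, and those intervals overlap. In TC-32 it was present at 73.1% (64.8 to 80.4%) and 74.4% (66.2 to 81.6%) of the same quartiles. Among the 20 highest-ranked sites, 18 were acetylated in TC-71 and 18 in TC-32, while 10 had an SMC1 peak in TC-71 and 14 in TC-32. The exception at the head of the list was 19p13.3 (chromosome 19, 605157 to 605921), a 765 bp peak with a fold enrichment of 31.4, which lay in none of the SMC1 and H3K27ac lists of either line. The next was 6p23 (chromosome 6, 13615421 to 13615613; fold 15.8), acetylated in both lines, with SMC1 in TC-32 alone. At 9q34.13 (chromosome 9, 134615495 to 134615651, fold 19.7) SMC1 was listed in both lines without H3K27ac at the site. The nearest H3K27ac domain was 276 bp from the BORIS summit in TC-71 and 314 bp in TC-32. At 19q13.2 (chromosome 19, 39420962 to 39421254; fold 15.3) both marks were listed in both lines. Others in this group were acetylated with no SMC1 peak in either line, as at 7q21.2 (chromosome 7, 92157868 to 92158094; fold 14.8) and 1p35.1 (chromosome 1, 32816799 to 32816995; fold 12.51).

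TC-71 BORIS sites lay at SMC1 and H3K27ac in TC-32 too, where few BORIS peaks were listed. In TC-32, 395 of the 534 sites lay at an SMC1 peak (74.0%, 70.03 to 77.6%) and 302 in an H3K27ac domain (56.6%, 52.2 to 60.8%). SMC1 was listed in both lines at 312 sites, in TC-71 alone at 30, in TC-32 alone at 83 and in neither at 109. H3K27ac was listed in both lines at 269 sites, in TC-71 alone at 34, in TC-32 alone at 33 and in neither at 198. Of the sites with SMC1 alone in TC-71, 91.6% (86.6 to 95.2%) had SMC1 in TC-32, and of those with H3K27ac alone 95.0% (89.97 to 98.0%) were acetylated in TC-32. In total 27 sites lay in none of the 4 SMC1 and H3K27ac lists. The higher SMC1 share in TC-32 turned around with lists of equal length, where it was 54.7% against 64.0% in TC-71.

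SMC1 peaks of the lines were compared next. Most cohesin sites of TC-71 were also sites in TC-32, while TC-32 sites were found in TC-71 mainly when they ranked high. Of the TC-71 SMC1 peaks, 90.3% (89.9 to 90.7%) overlapped a TC-32 peak, and of the TC-32 peaks 50.3% (49.8 to 50.8%) overlapped a TC-71 peak, against 0.556% and 0.307% by random placement. From the highest to the lowest rank quartile the TC-32 share fell from 91.4% to 65.3%, 33.7% and 10.8%, and the TC-71 share from 98.5% to 95.0%, 88.6% and 79.2%. With lists of equal length, which makes both shares nearly equal by construction, 74.7% of TC-32 and 74.9% of TC-71 peaks were shared. The highest-ranked SMC1 peaks listed in TC-32 alone were at 1q24.2 (chromosome 1, 168543452 to 168543825; fold 21.0), 5q23.1 (chromosome 5, 119991555 to 119991894; fold 29.0) and 1q43 (chromosome 1, 240618573 to 240618910; fold 14.2). Those listed in TC-71 alone were led by 6q25.2 (chromosome 6, 153633817 to 153634063; fold 10.4), 14q11.2 (chromosome 14, 22940555 to 22940849; fold 10.8) and 3p21.31 (chromosome 3, 46530232 to 46530571; fold 10.4). A second peak at 14q11.2 (chromosome 14, 22860334 to 22860658, fold 9.59) was also among the 10 named for TC-71. Among the 10 named for TC-32, further peaks on 1q lay at 1q25.2, 1q31.3 and 1q44, and others at 8p23.3, 4q31.23, 18q21.2 and 8p11.21. Copy number was not analysed here.

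Cohesin and acetylation met at different rates in shared and line-specific peaks. Of the TC-32 SMC1 peaks absent from the TC-71 list, 36.5% (35.8 to 37.3%) lay in a TC-32 H3K27ac domain, against 15.4% (14.8 to 15.9%) of shared ones. The difference grew down the list. The shares were 14.98% (12.4 to 17.8%) and 15.4% in the highest rank quartile, 19.4% (18.0 to 20.9%) and 14.96% (14.02 to 15.9%) in the second, 29.4% (28.2 to 30.6%) and 15.5% (14.2 to 16.9%) in the third, and 50.6% (49.4 to 51.7%) and 17.6% (15.2 to 20.3%) in the lowest. In TC-71 the shares were 17.0% (15.2 to 18.8%) of line-specific and 13.2% (12.7 to 13.8%) of shared peaks. By rank, they were 4.35% (0.906 to 12.2%) and 11.8% (10.9 to 12.8%) in the highest TC-71 quartile, 9.17% (5.77 to 13.7%) and 12.2% (11.2 to 13.2%) in the second, 12.7% (9.97 to 15.9%) and 11.8% (10.8 to 12.8%) in the third, and 22.1% (19.5 to 24.8%) and 18.0% (16.7 to 19.3%) in the lowest. With the SMC1 and H3K27ac lists of both lines cut to equal length, the line-specific and shared shares were 17.7% and 13.6% in TC-32 and 16.7% and 12.6% in TC-71. With a −log10 q of at least 5 they were 26.8% and 12.1% in TC-32, and 10.7% (9.25 to 12.3%) and 9.85% (9.38 to 10.3%) in TC-71. These alternatives were chosen after seeing the data.

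Over the whole lists, TC-71 H3K27ac domains were found in TC-32 less often than TC-71 SMC1 peaks were, and the gap lay mainly among weaker domains. For those with a −log10 q of at least 5, set against every peak of the other list, the shares were 88.5% for H3K27ac and 91.5% for SMC1. With this threshold in both lists they were 82.6% and 90.5%. Of the TC-71 domains 67.3% (66.7 to 67.9%) overlapped a TC-32 domain, and 47.1% (46.5 to 47.6%) of the TC-32 domains overlapped a TC-71 domain, against 4.59% and 3.28% by random placement. By bases, 27.8 Mb were covered in both lines, which is 65.1% of the TC-71 and 42.5% of the TC-32 covered sequence. High-ranked domains were largely common, at 92.5% in the highest quartile of TC-32 and 98.0% in that of TC-71, while the lowest quartiles reached 17.3% and 34.6%. The highest-ranked domains of TC-32 alone were a pair at 12q24.21 (chromosome 12, 114909629 to 114920588 and 114827841 to 114853565; fold 9.31 and 9.71), the band of the limb and heart transcription factor genes TBX3 and TBX5. Further TC-32 domains were at 3q24 (chromosome 3, 147109721 to 147114260; fold 9.34) and 13q34 (chromosome 13, 112720371 to 112728806; fold 10.6). In TC-71 the list was led by 17q25.3 (chromosome 17, 75522163 to 75525391; fold 9.94) and 14q23.1 (chromosome 14, 61103469 to 61106055; fold 8.47). Of the 10 domains named for TC-71 alone, 1 held a BORIS site, at 16q12.1 (chromosome 16, 47176717 to 47178334; fold 8.54).

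**Figure D2:**
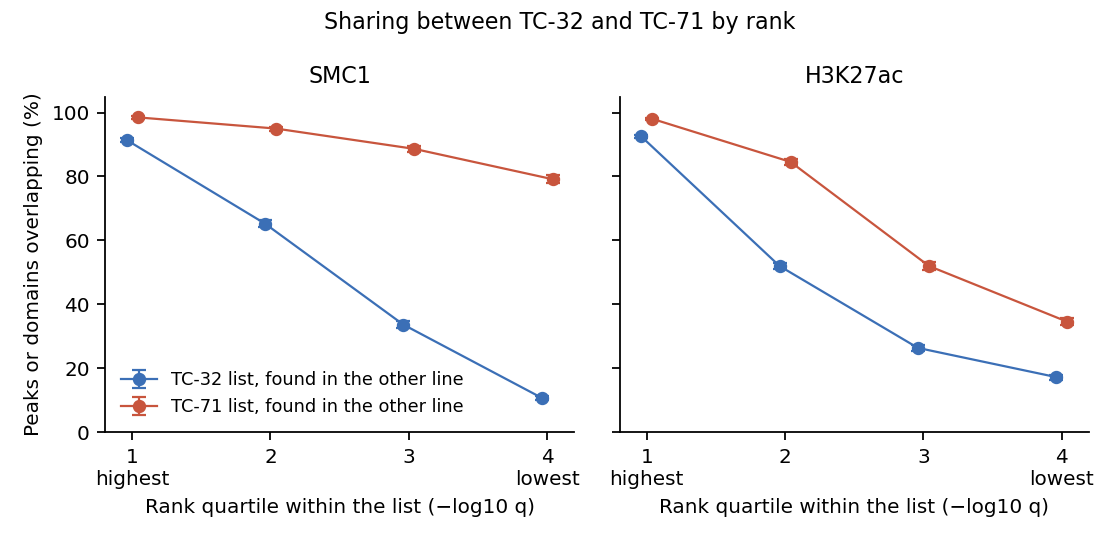
Share of SMC1 peaks (left) and H3K27ac domains (right) that overlap the list of the other line (vertical axis, percent), by rank quartile of −log10 q within the list (horizontal axis), for TC-32 (blue) and TC-71 (red), with exact 95% intervals. The highest quartiles lie between 91.4% and 98.5%, and the lowest TC-32 quartiles at 10.8% for SMC1 and 17.3% for H3K27ac.

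A further comparison asked whether BORIS lay more often at cohesin or acetylation sites that TC-32 lacks. Over the whole lists BORIS was not more frequent there: 1.58% (1.05 to 2.28%) of the SMC1 peaks listed in TC-71 alone held a BORIS site, against 1.90% (1.70 to 2.12%) of shared ones. For H3K27ac domains the shares were 0.221% (0.133 to 0.344%) in TC-71 alone and 1.58% (1.40 to 1.77%) when shared. With a −log10 q of at least 5 the SMC1 shares were 1.67% and 1.59%, the other way round, and the H3K27ac shares 0.907% and 1.97%. With 50% of a domain covered, 0.372% of domains in TC-71 alone held BORIS. BORIS sat in the higher-ranked, wider domains, with a median rank percentile of 85.4 against 49.5 elsewhere and a median width of 2033 bp against 1136 bp. Against domains elsewhere with the same ranks, those at BORIS were as often shared with TC-32, at 93.6% (90.3 to 96.1%) against 93.4%. The same held for SMC1 peaks, at 91.8% (88.4 to 94.5%) against 91.3%. By rank quartile the order for SMC1 peaks changed. BORIS lay at 0 of 69 peaks listed in TC-71 alone in the highest quartile and 0 of 229 in the second. Among shared peaks it lay at 114 of 4497 and 78 of 4337. In the lowest quartile BORIS lay at 20 of 952 (1.29 to 3.23%) in TC-71 alone and 56 of 3614 (1.17 to 2.01%) shared. Intervals overlapped within each quartile. Within the highest rank quartile of TC-71 H3K27ac domains the order differed from that over all domains. BORIS lay at 8 of 130 domains listed in TC-71 alone (6.15%, 2.69 to 11.8%) and at 209 of 6453 shared ones (3.24%, 2.82 to 3.70%), and the intervals overlap. Single bands could also differ. At 14q32.33, several of the 9 BORIS sites had SMC1 in TC-71 and not in TC-32, as at chromosome 14, 106765206 to 106765450. Among the 233 bands with more than 80 SMC1 peaks over both lines, only this 1 had more in TC-71 (75 against 63). It was singled out after its values were seen.

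Finally, neighbouring domains were stitched into clusters to find the stretches of densest acetylation, as is done for super-enhancers. TC-32 had 901 top clusters with a median span of 29.8 kb, and TC-71 had 670 with a median of 25.7 kb, holding 26.1% and 24.5% of the acetylated bases. The difference in number depended on the stitching distance, with 997 and 995 top clusters at 5 kb. Of the TC-32 clusters, 39.3% (36.1 to 42.6%) were also top clusters in TC-71, and 53.9% (50.02 to 57.7%) of the TC-71 clusters were top clusters in TC-32. Among the 10 highest-ranked, 8 of TC-32 and 9 of TC-71 were top clusters in the other line, and 3 bands appeared in both groups of 10. These were 22q13.31 (TC-32, chromosome 22, 46400272 to 46506685), 16q23.1 (TC-71, chromosome 16, 74513442 to 74659025) and 6p22.2 (TC-71, chromosome 6, 26086523 to 26207441), the band of the large replication-dependent histone gene cluster. The top 10 of TC-32 also included 11q13.3 (chromosome 11, 69426154 to 69498685), the band of the cyclin D1 gene CCND1, and 12q13.13 (chromosome 12, 54348415 to 54431058), the band of the HOXC homeobox genes. Whether the clusters overlap these genes was not tested here.

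Other clusters were top clusters in 1 line, with or without domains in the other. In TC-32, the clusters at 7q32.3 (chromosome 7, 130564545 to 130656133) and 19p13.2 (chromosome 19, 13093857 to 13207656) were ranked 4 and 5 and were not top clusters in TC-71. In TC-71, the cluster ranked 5 at 7p21.1 (chromosome 7, 18531310 to 18631312) covered 75.6 kb and was not a top cluster in TC-32. No TC-71 domain lay in 83 of the 901 TC-32 clusters (9.21%, 7.40 to 11.3%), and no TC-32 domain in 24 of the 670 TC-71 clusters (3.58%, 2.31 to 5.28%). The highest-ranked of these in TC-32 was at 12q24.21 (chromosome 12, 114803379 to 114853565), with a neighbour at 114867675 to 114920588, followed by 3p22.3 (chromosome 3, 35674653 to 35729628) and 13q34 (chromosome 13, 112710749 to 112759445). In TC-71 they were led by 4p15.31 (chromosome 4, 20298166 to 20340027) and 10p12.1 (chromosome 10, 26013711 to 26046587). Of the 303 acetylated TC-71 BORIS sites, 43 (14.2%, 10.5 to 18.6%) lay in a TC-71 top cluster, against 13.4% of all TC-71 domains and 24.5% of acetylated bases. None of the 10 highest-ranked TC-71 clusters held a BORIS site.

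**Figure D3:**
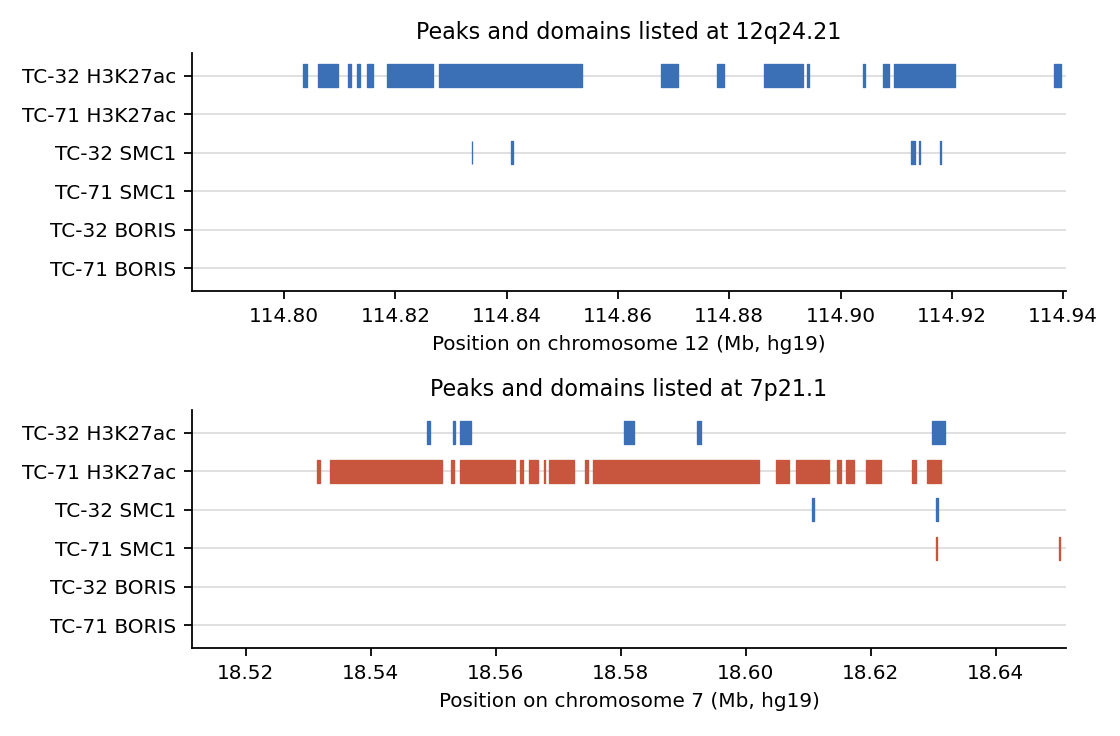
Peaks and domains listed in each line (rows; TC-32 blue, TC-71 red) at 12q24.21 and 7p21.1, with hg19 positions in Mb on the horizontal axis. In the 12q24.21 window TC-32 has 15 H3K27ac domains covering 65.4 kb and 5 SMC1 peaks while TC-71 has 0 of each, and in the 7p21.1 window TC-71 has 17 domains covering 75.6 kb against 6 covering 6.69 kb in TC-32.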

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

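No paired analysis was possible because the lists hold no values per replicate; leaving out a replicate was not possible for the same reason. Of 78 alternative values, 41 stayed within the interval of the main share or within 1.5 times the main count, and 37 moved, 12 of them in the BORIS and H3K27ac shares of shared and line-specific peaks. The alternatives for H3K27ac at SMC1 peaks were chosen after seeing the data. A −log10 q of at least 5 left 3 TC-32 BORIS peaks. Applied to the SMC1 and H3K27ac lists, with all 534 TC-71 BORIS sites kept, it put SMC1 in TC-32 at 69.9% of these sites. Applied to the BORIS peaks instead, it gave 72.7% of 458 sites. In the comparison of the lines this threshold in both lists gave shared shares of 52.6% (TC-32 SMC1), 82.6% (TC-71 H3K27ac) and 56.3% (TC-32 H3K27ac). Against every peak of the other list it gave 91.5% and 55.6% for SMC1 of TC-71 and TC-32, and 88.5% and 66.5% for H3K27ac. With 50% of the peak covered, shared shares were 44.8% (TC-32 SMC1), 60.2% (TC-71 H3K27ac) and 37.7% (TC-32 H3K27ac). Lists of equal length gave 54.7% of BORIS sites with SMC1 in TC-32, 74.9% and 74.7% of TC-71 and TC-32 SMC1 shared, and 61.4% and 58.3% for H3K27ac; removing the lowest-ranked TC-32 peaks changes these by construction. A 500 bp window from the BORIS summit raised H3K27ac to 69.7% in TC-71 and 67.8% in TC-32. Merged domains were shared at 69.1% (TC-71) and 48.2% (TC-32). Shared top clusters were 43.5% (TC-32) and 44.6% (TC-71) with 5 kb stitching, and 35.6% and 45.0% when ranked by covered length, from 997 and 995, and 912 and 742 clusters. The cause of the other shifts was not tested. Promoter, gene list, motif and TSS-excluding settings were not run. Unknown read depth limits every comparison of list lengths.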

Other observations

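The peak density was lower in the darkest than in unstained chromosome bands, most steeply for BORIS. TC-71 BORIS sites numbered 0.279 per Mb in unstained, generally gene-rich bands and 0.0421 per Mb in the darkest bands, with 67.4% (63.3 to 71.4%) of the sites in unstained bands that make up 42.4% of the sequence. SMC1 fell from 7.88 to 3.12 peaks per Mb between the same classes in TC-71 and from 13.1 to 8.02 in TC-32. The fall was not steady, since the lightest stained bands were denser than unstained ones, at 9.03 SMC1 peaks per Mb in TC-71 and 14.3 in TC-32. For H3K27ac they had 12.3 against 11.1 domains per Mb in TC-71 and 17.5 against 15.5 in TC-32. Among the 233 bands with more than 80 SMC1 peaks in both lines together, the highest ratios of TC-71 to TC-32 acetylated domains were in 2 bands of 8q. Band 8q23.3 held 100 H3K27ac domains in TC-71 and 39 in TC-32, and 8q24.21, the band of MYC, held 134 and 87. Over the 233 bands the median ratio was 0.75, and 34 had more domains in TC-71. SMC1 did not follow, with 21 peaks in TC-71 and 60 in TC-32 at 8q23.3, and 40 and 72 at 8q24.21. The opposite extreme of these bands was 11q25, with 10 domains in TC-71 and 61 in TC-32, and then 18q11.2, with 19 and 81. These bands were singled out after their values were seen. Chromosome 8 as a whole had the highest ratio of TC-71 to TC-32 H3K27ac domains among the chromosomes, at 0.867. Copy number was not analysed here.

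High-ranked domains and peaks without a counterpart in the other line formed runs in several places. At 1q44 (chromosome 1, 247611199 to 248865921), 7 consecutive domains of the highest TC-32 rank quartile had no TC-71 counterpart, and 27 TC-32 domains in the stretch faced 0 in TC-71, while SMC1 peaks there numbered 15 in TC-32 and 1 in TC-71. A run as long occurred in 0 of 1000 shuffles of shared and missing domains. At 18p11.32 (chromosome 18, 361302 to 635767) the run was 6 domains, reached in 1 of 1000 shuffles, with 23 TC-32 domains and 1 TC-71 domain, and with 10 and 3 SMC1 peaks. At 19p12 (chromosome 19, 20011139 to 20844415), 5 consecutive domains were missing, and 13 of 1000 shuffles gave a run as long; 9 domains and 3 SMC1 peaks in TC-32 faced 0 domains and 1 SMC1 peak in TC-71. The longest TC-71 run was 4 domains at 8q23.2 (chromosome 8, 110702873 to 112458743), reached in 1 of 1000 shuffles, but the stretch was not empty in TC-32, with 11 domains there against 46 in TC-71. A run of 6 TC-32 SMC1 peaks at 7q21.11 (chromosome 7, 80328392 to 81586160) was also reached in 1 of 1000 shuffles, and TC-71 had 3 SMC1 peaks and 8 domains in this stretch. These runs were chosen after the data were seen, and apart from chance, by these shuffles, no cause was tested. Copy number was not analysed here. Runs are likelier where the rate of missing peaks is high, and for SMC1 that rate was not even across band classes.

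Of the tests that follow, those of peak rank, of the TC-71 SMC1 threshold and of chance scatter were chosen only after the result was seen. SMC1 peaks listed in TC-32 alone lay at H3K27ac more often than shared ones, at 36.5% against 15.4%. Lower rank alone is argued against, since against shared peaks of the same rank deciles the difference was 19.8 percentage points (36.5% against 16.7%). With the SMC1 lists alone cut to equal length the difference was 3.99 percentage points (19.1% against 15.1%), but this removes the lower-ranked TC-32 peaks, where the difference was largest, so an effect of the shorter TC-71 list cannot be told apart from their rank range. The lines' own acetylation may contribute, as a hypothesis: the share of these acetylated peaks without a TC-71 domain was 15.8 percentage points higher for TC-32-only than for shared peaks (45.8% against 30.0%). This contrast was not matched for rank. Counted by domain rather than by SMC1 peak, 19248 of all 36355 TC-32 domains had no TC-71 domain. Both of the latter explanations remain open.

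Some of the highest-ranked TC-71 BORIS sites carried H3K27ac and no SMC1 peak. H3K27ac without SMC1 was found at 36.6% (28.4 to 45.3%) of the highest rank quartile and 21.05% (14.5 to 29.0%) of the lowest. The quartiles between had 28.6% and 18.7%, and the intervals of the highest and lowest quartiles meet. An SMC1 peak was listed in TC-71 at 56.7% of the highest quartile. Whether SMC1 lies just below the threshold of the short TC-71 list at such sites cannot be told: 43.6% (35.2 to 52.2%) of all of them and 53.1% (38.3 to 67.5%) of the 49 in the highest quartile had an SMC1 peak in TC-32, but so did 42.3% (28.7 to 56.8%) of the sites with neither mark in TC-71. SMC1 in the longer TC-32 list was as frequent at high as at low BORIS rank, with 73.1% in the highest and 74.4% in the lowest quartile, which leaves this explanation open. Unspecific signal that grows with acetylation remains a candidate explanation: BORIS was found in 0.106% of the lower 50% of TC-71 domains, in 4.26% (3.48 to 5.15%) of the 9% below the top 1%, and in 7.20% (4.39 to 11.01%) of the top 1%. It cannot be told apart from BORIS binding at active sites, because the intervals of the highest groups meet and binding would give the same order, and no biological explanation was tested. The shares were counted per domain and not adjusted for width. Domains with BORIS were wider than those elsewhere, at a median of 2033 bp against 1136 bp, so width may contribute to the order as well.

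On 5q23, 8 consecutive SMC1 peaks of the highest TC-32 rank quartile had no TC-71 counterpart (chromosome 5, 119793970 to 125570579, 5.78 Mb), and in the bands of 5q23 as a whole 15 of 24 such peaks were missing (62.5%, 40.6 to 81.2%). Scatter by chance at an even rate is unlikely, since 0 of 1000 shuffles gave a run as long and the longest was 6. The missing rate was not even across band classes, as given below, which makes long runs likelier than in such shuffles. The 10 TC-71 peaks inside this stretch, 3 of SMC1 and 7 of H3K27ac, argue only against its absence as a whole from TC-71. In TC-32 it held 60 SMC1 peaks and 46 H3K27ac domains. Absence of a part of the stretch from TC-71 stays open, because a few remaining peaks cannot speak against it. Missing peaks were more frequent with staining, from 7.21% in unstained bands to 10.5% (8.59 to 12.7%) in the second-darkest and 16.8% (14.1 to 19.7%) in the darkest bands. These shares include the peaks of 5q23 itself. Outside 5q23 the share in both dark classes together was 12.8% (11.2 to 14.5%), which argues against such a general loss as the whole cause. Part of 5q23 is also not dark-staining, so dark staining could not account for the whole run. Absence of sequence also stays open for a neighbouring run of 5 peaks at 5q23.1 (chromosome 5, 115893430 to 118128065, 25 of 1000 shuffles). There 0 TC-71 peaks face 14 SMC1 peaks and 9 H3K27ac domains in TC-32. For both runs a difference in cohesin binding or copy number stays open as well, and it was not analysed here.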
